A study of Drosophila melanogaster with 2 samples.

How the data were processed

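The series measured gene expression in whole adult female Drosophila melanogaster of the Oregon-R wild-type strain, aged 4 to 10 days, after a fine spray of ethanol or of water. The spray was 2 mL of 99% ethanol or of distilled water, delivered in a Potter tower, a device that settles an even mist on insects. The labels also record a rinse with 80% ethanol for both arrays, and its step is not detailed here. Per the labels' protocols, each RNA extract came from about 240 flies and 80 µg of total RNA was labelled directly for each hybridisation. The time from spray to sampling is given as 4 h in the series text and as 6 h in the label of replicate 1, and the label of replicate 2 gives none, so it stays open between these values. Each of 2 spotted 2-colour arrays carried 1 ethanol extract and 1 water extract, and the dyes were exchanged: ethanol was labelled with Cy3 on array 1 and with Cy5 on array 2. The 2 arrays are biological replicates in the series text, so both replicate spread and dye are confounded in the difference between them.

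The authors deposited 1 signed log ratio per spot and array, which was read here as log2. The background correction, the normalization, the base of the logarithm and the direction of the ratio are not given in the sources used here. The values were read as log2 because they were signed, had medians of -0.0009 and 0.0002 on arrays 1 and 2, and ran from -14.6 to 10.7, and a natural-log reading was tried as an alternative. The labels list water as channel 1 and ethanol as channel 2 on both arrays, whatever the dye. The values were therefore first taken to run the same way on both arrays. The gene fit, fold counts, list tests and spot filters were computed again with array 2 turned in sign. That is the right coding if the values are Cy5 over Cy3. Other centring and scaling, robust eBayes, the fit over all clones and some of the checks were run with the first coding only. Since no header settles the coding, values are given as positive or negative deposited ratios, and none is called higher in ethanol or in water. Spot intensities were not used here, so signal over background is unknown for every spot, and the number of arrays limits the precision.

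The table held 16896 spots, each with a value on both arrays. They were taken as 8448 pairs of adjacent spots, each pair called a clone here. The 2 spots shared their annotation in all 2909 annotated pairs, and the other pairs were assumed to be duplicates from their position. Gene names came from the platform annotation through Entrez gene identifiers: 5666 spots had 1 gene symbol, 152 had several and 11078 had none, and all 2377 genes with a symbol of their own matched the current gene table. No genome coordinates are given, because no source ties the clones to a genome build. The spots of a clone were averaged, then the clones of a gene, which numbered 1 for 2089 genes and 2 or more for 288. Spots with several symbols or none were left out of gene counts. Control spots are not marked in the files used here, so a control with a gene symbol counts as that gene.

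Ethanol was compared with water in 1 limma fit over both arrays, with the mean ratio tested against 0 by lmFit and eBayes and Benjamini-Hochberg adjustment over 2377 genes (limma 3.58.1, R 4.3.3). With 2 arrays no dye term could be fitted, and a permutation of signs cannot give a two-sided p below 0.5, so the test rests on the spread that limma shares across genes. Genes of 1.5-fold or more (0.585 on the log2 scale) on both arrays were counted and set against 10000 shuffles of the genes of array 2. Of 22 gene lists fixed before the data were examined, 13 had at least 4 measured members and were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Errors are SDs over the 2 arrays (n = 2).

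The genes named were also fixed by a rule before the data were examined: those of 1.5-fold or more on both arrays with one sign (up to 10 on each side), those with opposite signs (up to 5 on each side), up to 10 past an adjusted p of 0.05, and from each tested list the 2 members of largest mean size, or up to 4 where the list passed. Other names are marked as chosen after their values were seen. Alternatives were other centring and scaling of the arrays, other fold thresholds, medians of spots, robust eBayes, duplicate spots kept with duplicateCorrelation, an estimated correlation in camera, random lists, and each array alone. Filters on extreme or discordant spots, a count over all clones and the natural-log reading were added after seeing the data. Adjustment of p over the members of a single list was not among the planned tests, and was not corrected over the lists. The test was checked on simulated data, in which each array's values were shuffled over the 2377 genes and 200 genes were changed on both arrays, 50 at each fold. It recovered 27.6% of the changes of 1.5-fold, 88.9% of 2-fold, 98.9% of 3-fold and 99.7% of 4-fold, with 11.8 false calls per set on average over 20 sets. These rates hold for 200 genes changed at once on both arrays. They are not the power for fewer changed genes or for changes weaker on array 2. Where no gene was changed, 100 shuffles of the genes of array 2 gave 4.69 calls on average, with a median of 0. Checks and plots used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.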

Results

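To assess the effect of topical ethanol on gene expression, RNA from ethanol-sprayed females was hybridised against RNA from water-sprayed females on 2 arrays with exchanged dyes. Each array gave 16896 deposited ratios, read as log2, and 2377 genes could be named. The interquartile range of the spots ran from -0.22 to 0.22 on array 1 and from -0.25 to 0.25 on array 2. Array 1 held 64 spots of more than 3 in size and array 2 held 8.

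The precision of the arrays was first read from the 2 adjacent spots of each clone. On array 1 the 2 spots agreed, with a Spearman rho of 0.60 over 8448 clones and a median difference of 0.161. On array 2 rho was 0.12 and the median difference 0.316. Over named clones alone, rho was 0.57 on array 1 and 0.10 on array 2. Neighbouring spots of different clones gave a rho of 0.13 on array 1 and 0.074 on array 2. The covariance of duplicate spots, with values limited to 3 in size, corresponded to a shared SD of 0.34 on array 1 and 0.13 on array 2. That SD holds differences between clones together with any variation shared by neighbouring spots, which was not subtracted. The rho values and covariances were taken across clones, which are not independent replicates.

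**Figure D1:**
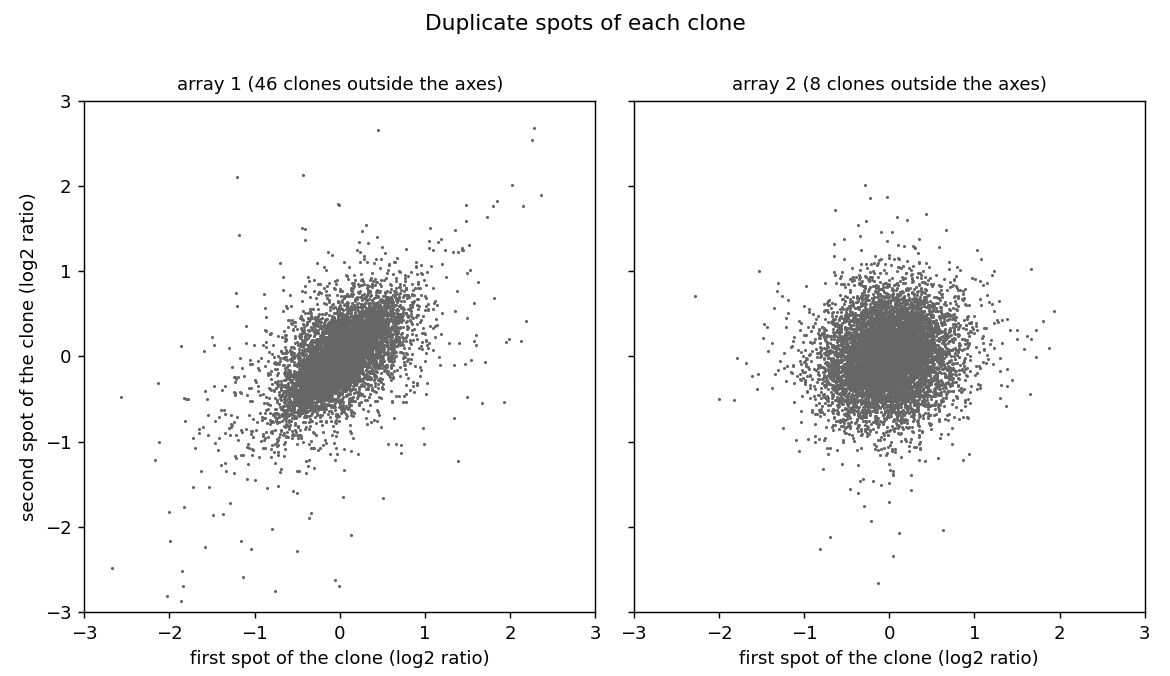
Deposited log2 ratio of the first spot of each clone (x axis) against the second spot (y axis), on array 1 (left) and array 2 (right), 1 point per clone. The points lie along the diagonal on array 1 (Spearman rho 0.60) and form a round cloud on array 2 (rho 0.12).

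No gene passed an adjusted p of 0.05 between ethanol and water (limma, Benjamini-Hochberg over 2377 genes, lowest adjusted p 0.27). Only 3 genes were 1.5-fold or more from equality on both arrays with one sign, or 36 if the values are natural logs. CG15109 was positive, at 0.76 ± 0.02 (SD, n = 2), as was Rsph3, which encodes a radial spoke protein of the ciliary axoneme, at 0.72 ± 0.19, although duplicate spots of Rsph3 differed by up to 1.91. Hs6st, a heparan sulfate 6-O-sulfotransferase, was negative at -0.67 ± 0.02. Another 3 genes passed 1.5-fold on both arrays with opposite signs. These were Sod3, an extracellular superoxide dismutase, at 1.02 on array 1 and -0.71 on array 2, the cuticle protein gene Lcp65Ag3 at -0.996 and 0.67, and CG15169 at -0.79 and 0.65.

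Both counts lay within what unrelated arrays give. Shuffling the genes of array 2 gave on average 3.48 genes with one sign and as many with opposite signs, with central 95% ranges of 0 to 7. Read as natural logs, the values gave 36 genes with one sign and 24 with opposite signs, and the shuffles 28.9 and 29.0, each with a range of 19 to 39. At a lower threshold of 0.322 on the log2 scale, 82 genes had one sign and 66 opposite signs, against a shuffled mean of 69.5 and 69.1, and a share of 0.0572 of the shuffles gave at least 82. At 2-fold there were none of either kind, although 34 genes passed on array 1 alone and 7 on array 2 alone. At an unadjusted p under 0.05, limma counted 136 genes, 69 positive and 67 negative, against 118.8 from chance. With array 2 turned in sign it counted 95, and again no gene passed adjustment (lowest adjusted p 0.94). The fit with duplicate spots kept made 0 calls among 2833 clones, with 211 at an unadjusted p under 0.05, and 206 with array 2 turned in sign. The chance count of 118.8 is for 2377 genes and does not apply to these clones. Their counts were similar under both codings, so they do not favour either. Filters added after seeing the data made calls: limma called 8 genes without clones holding a spot over 3 in size and 5 among clones whose spots differed by at most 0.5 (concordant clones). Of 100 shuffles of the genes of array 2, 10 and 18 gave at least as many. With array 2 turned in sign, the first filter gave 0 genes (lowest limma adjusted p 0.216, with 116 at an unadjusted p under 0.05). The second then gave 3 genes (alphaTub85E, Hsc70-2 and Sod3, named after their values were seen). With that coding 30 of 100 shuffles gave at least as many.

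Across named genes no relation between the 2 arrays was seen, with a Pearson r of 0.026 (95% bootstrap interval -0.012 to 0.063) and a Spearman rho of 0.0034 (-0.038 to 0.041). Genes are not independent replicates, so the intervals describe these 2 arrays. Over all 8448 clones, named or not, rho was -0.037, and 0.888% of the 8447 other alignments of array 2 in print order gave a rho as large in size, a test chosen after the value was seen. The sign of this weak relation turns with the coding of array 2. The 95% confidence interval of a gene's mean ratio reached a median of 0.41 to either side on the log2 scale.

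**Figure D2:**
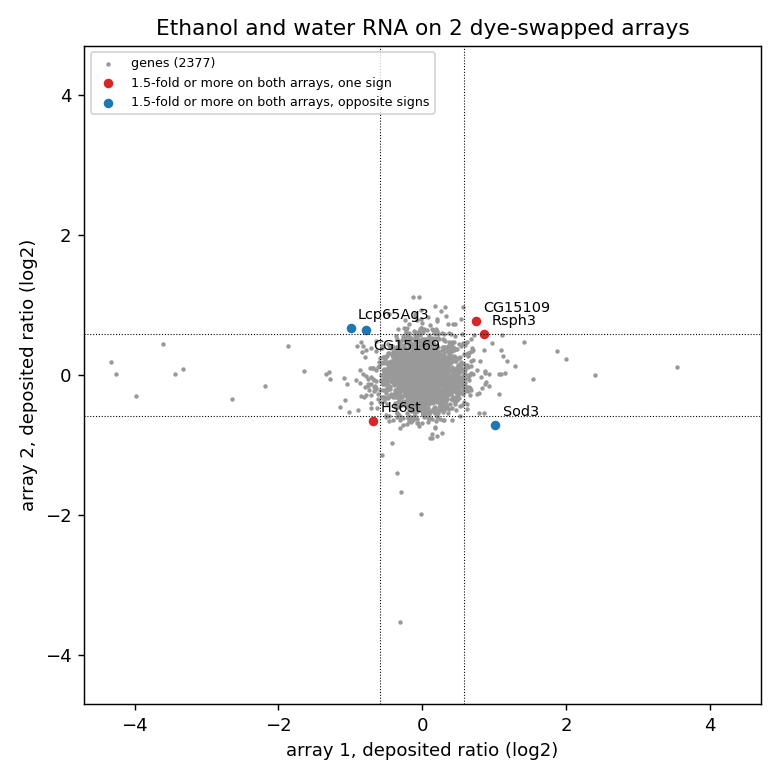
Deposited log2 ratio of each of 2377 genes on array 1 (x axis) and array 2 (y axis), with dotted lines at 1.5-fold. The 3 genes past the lines with one sign (red) and the 3 with opposite signs (blue) lie at the edge of a round cloud, and the genes farthest out are extreme on 1 array only.

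Among the stress genes, chaperones of the Hsp70 family were called over their list with both arrays taken to run the same way. The antioxidant gene Sod3 was called over its list with array 2 turned in sign. This adjustment over single lists was not planned and was not corrected over the lists. Hsc70-2, a cognate of Hsp70, was positive on both arrays, at 1.11 ± 1.08 (SD, n = 2), with 1.87 on array 1 and 0.34 on array 2. The stress-inducible Hsp68 was at 0.94 ± 0.67, with 1.42 and 0.47. Their means were 0.77 and 0.47 with array 2 turned, against 0.86 for Sod3. Adjusted over the list alone, 3 of the 9 measured heat shock proteins and chaperones passed 0.05, all positive: Hsc70-2 and Hsp68 (limma adjusted p = 0.0039 each) and Hsc70-1 (0.0171). None of the 9 passed over all genes tested (limma adjusted p = 0.27 for Hsc70-2 and Hsp68, 0.42 for Hsc70-1). With this coding, though, Hsc70-2 and Hsp68 passed under both added filters, and Hsc70-1 among concordant clones only (mean 0.91, limma adjusted p = 0.0025). With array 2 turned, Hsc70-2 passed among concordant clones only, at a mean of 0.88 (limma adjusted p = 0.018). Of the 9 members, 4 were positive and 4 negative on both arrays, with Hsp60B, a mitochondrial-type chaperonin, at -0.56 ± 0.74 and DnaJ-1, a co-chaperone, at -0.35 ± 0.04. Hsc70-1, Hsp60B and DnaJ-1 were named after their values were seen. The list as a whole did not pass, with a median of 0.28 on array 1 and -0.00067 on array 2 (camera adjusted p = 0.26). Family members of similar sequence may cross-hybridise, which was not tested, so these values are uncertain as to which gene they report. Of 100 shuffles of the genes of array 2, 34 gave at least 3 calls in this list, so array 1 can bring about such a count without a match on array 2. The calls also depended on the sign of array 2, since with array 2 turned the list held 0 (lowest limma adjusted p over the list 0.321).

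None of the other 12 tested lists passed either (lowest camera adjusted p 0.18, and 0.88 with an estimated correlation). The circadian clock genes were negative on both arrays in 4 of 4 members, with medians of -0.22 and -0.069 (adjusted p = 0.18, and 0.82 with array 2 turned in sign, where Clk was at 0.074). In this list cwo, a transcriptional repressor of the clock, was at -0.40 ± 0.55 and Clk, the clock activator, at -0.26 ± 0.11. The 20 odorant binding proteins had medians of -0.025 and 0.0028 (adjusted p = 0.18). Obp84a was the farthest at -1.71 ± 2.44, with -3.44 on array 1 and 0.017 on array 2, and both of its array 1 spots exceeded 3 in size and lay beside another clone with such a spot. The median of the list's means was -0.077, and -0.0037 without clones holding such a spot. Obp99a was negative on both arrays, at -0.56 ± 0.22. Adjusted over their lists alone, limma called Obp84a among the odorant binding proteins (adjusted p = 0.0484) and Obp99a among the 4 fat body genes (0.0435) but not among the odorant binding proteins, and neither over all genes (0.30 and 0.55). The call of Obp84a was lost with other centring or scaling and with robust eBayes, while that of Obp99a was kept. With array 2 turned in sign neither was called over its list, and limma instead called Sod3 among the antioxidant genes (adjusted p = 0.00543), Lcp65Ag3 among the cuticle genes (0.00424) and the troponin C gene TpnC41C among the muscle genes (0.0369), the last named after its value was seen. None of these 3 passed over all genes with array 2 turned (lowest adjusted p 0.94), although Sod3 passed among concordant clones (0.018). In all, 5 list members were called over their lists with both arrays run the same way, and 48 of 100 shuffles of the genes of array 2 gave at least as many (mean 4.24). The count was 4 with other centring or scaling, 3 with robust eBayes, 9 without clones holding a spot over 3 in size and 5 among concordant clones. The first filter added calls of Hsp60B, Sod2, RpS10a, Tm2 and TpnC73F, and lost that of Obp84a, whose clone it removed. Sod2 and RpS10a were also called among concordant clones, where neither Obp84a nor Obp99a was. With both arrays run the same way, 2 genes passed when adjusted over the 87 genes of the tested lists together (limma, lowest adjusted p 0.038). Neither the shuffles of these calls over single lists nor this joint adjustment was run with array 2 turned. Of 7 antioxidant genes, Sod2, the mitochondrial superoxide dismutase, was at 0.69 ± 0.68 and the glutathione peroxidase gene Gtpx at -0.45 ± 0.43, and the list had an adjusted p of 0.74.

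Among detoxification genes, 5 matched the cytochrome P450 list (adjusted p = 0.74) and 7 were UDP-glycosyltransferases (0.83). Cyp4ac1 was at -0.34 ± 0.29. Cyp1, at 0.24 ± 0.16, entered the P450 list by its name only, since it encodes a cyclophilin. Ugt50B3 was at -0.11 ± 0.23 and Ugt35A1 at 0.05 ± 0.57. The UDP-glycosyltransferase list had a median of 0.0018, while its mean and its test lay on the negative side. With array 2 turned in sign, the median opposed the mean or the test in the cuticle, P450, fat body and odorant binding lists. Of 6 genes tied to ethanol sensitivity or tolerance, kra, a translational regulator, was at 0.42 ± 0.04 and dlg1, a synaptic scaffold, at 0.06 ± 0.16, and the list had an adjusted p of 0.74. The 4 cuticle genes (0.74) included Cpr47Ee at -0.11 ± 0.06 beside Lcp65Ag3. Of 6 ribosomal protein genes (0.74), RpS10a was at 0.74 ± 1.13 and RpS15Ab at -0.41 ± 0.11.

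Markers of single tissues were tested in the same way, because whole flies mix many cell types. Muscle genes were negative on array 1 in 6 of 7 members and on array 2 in 2 of 7, with medians of -0.47 and 0.077 (adjusted p = 0.45, and 0.091 with array 2 turned in sign). Tm2, a tropomyosin, was at 0.70 ± 0.82 and the troponin C gene TpnC73F at -0.53 ± 0.35. Eye genes were negative on array 1 in 4 of 4 members and positive on array 2 in 3 of 4 (adjusted p = 0.74, and 0.16 with array 2 turned). The lipase gene inaE was at -0.15 ± 0.05 and the diacylglycerol kinase gene rdgA at -0.07 ± 0.24. Fat body genes had medians of -0.094 and -0.17 (adjusted p = 0.36), with Fbp2 at -0.19 ± 0.56. Markers of male accessory gland and testis, included to look for a difference in male content between the extracts, had medians of -0.019 and 0.11 (camera adjusted p = 0.74). Of these, the seminal protein gene Acp36DE was at 0.49 ± 0.23 and Mst84B at -0.42 ± 0.05. Males present equally in both extracts would not show in a ratio, so these values cannot tell how well the females were sorted.

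The remaining 9 lists had fewer than 4 measured members and were not tested, and their members were named after their values were seen. Glycolysis, starvation response and midgut protease genes had 0. Alcohol and aldehyde metabolism had only the aldehyde dehydrogenase gene Aldh-III, at 0.11 ± 0.39. The glutathione S-transferases were GstE13 at -0.26 ± 0.02, GstE2 at -0.11 ± 0.07 and GstZ2 at -0.13 ± 0.24. The immune gene Tep4 was at 0.08 ± 0.27, and yl, the yolk protein receptor of the ovary, at -0.14 ± 0.06. The lipid droplet genes Lsd-2 and bmm were at -0.06 ± 0.48 and 0.07 ± 0.46. The neuronal genes cac, nSyb and nrv3 were at 0.20 ± 0.09, 0.13 ± 0.30 and -0.10 ± 0.01.

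**Figure D3:**
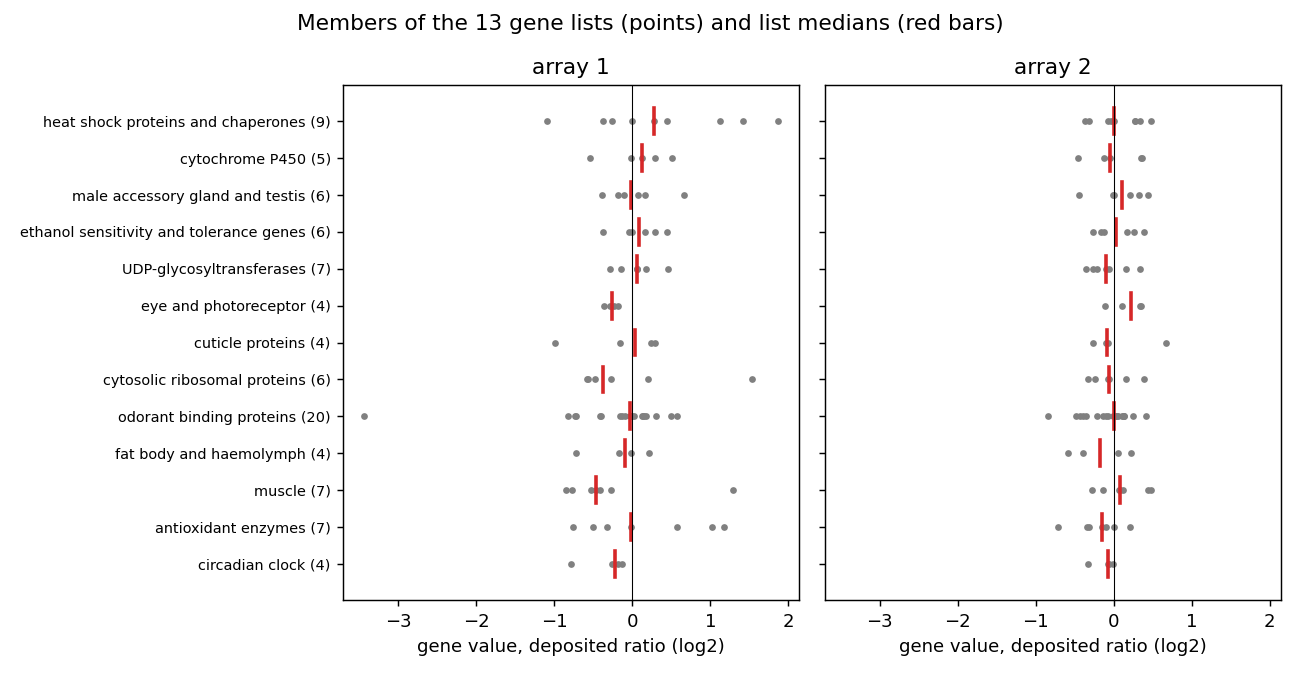
Deposited log2 ratios of the members of the 13 tested gene lists on array 1 (left) and array 2 (right), 1 point per gene, with the median of each list as a red bar and the number of members in parentheses. The medians run from -0.47 (muscle) to 0.28 (heat shock) on array 1 and stay between -0.17 and 0.22 on array 2.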

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

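The filters on wide or discordant spots, the count over all clones and the natural-log reading were chosen only after the result was seen. The 2 arrays gave a Spearman rho across genes between -0.037 and 0.013 under the other settings. No gene passed a limma adjusted p of 0.05 with array 2 turned in sign, other centring or scaling, robust eBayes, duplicate spots kept or all clones. Where counted, limma gave an unadjusted p under 0.05 to 95 to 137 of 2377 genes. The count was 211 of 2833 named clones with duplicate spots kept and 395 of all 8448 clones. Leaving out clones with a spot over 3 in size gave 8 genes, and keeping only clones whose spots differed by at most 0.5 gave 5. With array 2 also turned in sign, these became 0 and 3. The lowest adjusted p over the limma settings, changed 1 at a time, ran from 4.76e-06 to 0.942. The prior degrees of freedom that limma estimates rose from 14.8 to 76.8 without the wide spots and became infinite among concordant clones, where the test then ignores a gene's own spread. Genes of 1.5-fold or more on both arrays with one sign numbered 5 after scaling the arrays to a common spread, 1 among concordant clones, 15 among all clones (with 19 of opposite sign), 36 with values read as natural logs, 82 at the lower threshold of 0.322 and 0 at 2-fold. On 1 array alone the count was 113 to 146. With settings changed 1 at a time, the gene lists gave 0 calls except for 1 among concordant clones (heat shock, camera adjusted p = 5.86e-05) and 3 lists outside the central 95% of random lists (heat shock, antioxidant and clock, or muscle and eye with array 2 turned), and the lowest adjusted p ran from 5.86e-05 to 0.88. With an estimated correlation the heat shock call was lost (adjusted p = 0.84), and 29 of 100 shuffles of the genes of array 2 gave as low a list p. Among concordant clones with array 2 turned, camera called heat shock (adjusted p = 3.31e-05) and muscle (0.031). Both calls were lost with an estimated correlation (camera adjusted p = 0.96 each). With that coding 20 of 100 shuffles gave as low a list p. The heat shock count of 3 over the list alone became 0 with array 2 turned in sign. With robust eBayes it became 2, as Hsc70-2 was no longer called. Without the wide spots it became 4, and Hsp60B was called on the negative side (-0.56). The cause of these changes was not tested. With array 2 turned, the test's direction turned for antioxidant enzymes (median 0.16), male glands (-0.011) and UDP-glycosyltransferases (0.079), and CG15109 moved to -0.015. Among concordant clones the test's direction turned for P450 (0.040) and ribosomal genes (-0.058). None of these lists passed in either direction. The filters on measured spots removed no gene. Signal over background was not used here, so its limits are unknown. The exact sign permutation cannot pass. With 1 array no test could be made of genes or lists. The ratio within each array already pairs its ethanol and water RNA.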

Other observations

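The tests of row order, of a fixed shift, of spot noise on array 2, of chance for the Hsp70 family and of patches among wide ratios were chosen only after the result was seen, as was the filter on spots over 3 in size. The genes named here were likewise chosen after their values were seen.

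Several clones printed at different places report the same gene. RpL32, a ribosomal protein gene, had 9 clones, all negative on array 1 with a mean of -0.58 ± 0.19 (SD over clones), while 5 of 9 were negative on array 2 with a mean of -0.07 ± 0.29. The 8 clones of DnaJ-1 averaged -0.37 ± 0.69 on array 1 and -0.32 ± 0.45 on array 2. Without clones holding a spot over 3 in size, limma called Hsc70-2, Hsp68, Mos (a germline kinase) and alphaTub85E (a tubulin) on the positive side, and CG9920, CG6683, Camta and und on the negative side, with both arrays taken to run the same way. The filter gave 0 genes with array 2 turned in sign (limma, lowest adjusted p 0.216, with 116 at an unadjusted p under 0.05). Of 100 shuffles of the genes of array 2, 10 gave at least 8 calls under this filter with the first coding, and the highest gave 11. alphaTub85E was at 2.40 on array 1 and -0.0032 on array 2, so its call came from array 1 alone.

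The Hsp70 family lay on one side on both arrays. Its 3 measured genes, Hsp68, Hsc70-1 and Hsc70-2, were represented by 6 clones, all positive on both arrays, in 12 of 12 spots on array 1 and 11 of 12 on array 2. The clones ran from 0.33 to 1.96 on array 1 and from 0.16 to 0.48 on array 2. Local patches on the slides are argued against, since 36 surrounding clones had a median of 0.0376 on array 1 against 1.55 for the 6 clones. Surrounding clones were the nearest in print order and those 1 row away, with the row length read from the values. The mean of the 3 genes on array 2, 0.361, lay at percentile 98.7 of 10000 random sets of 3 genes, but the genes were singled out from these arrays, so chance stays open. A response of these genes to ethanol stays open, as untested. A dye effect cannot be told apart from it, because the sources used here do not say whether the deposited ratio follows the channel or the dye. Cross-hybridisation between family members was not tested, so which of them a ratio reports stays open.

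The agreement of duplicate spots differed between the arrays, with a Spearman rho of 0.60 on array 1 and 0.12 on array 2. A complete shuffle of the row order on array 2 is argued against by spots 24 positions apart. Their rho of 0.0507 is far above the 0.0077 SD of a shuffled order. This distance was taken as 1 printed row because it gave the largest rho among the distances tried on each array, not from a label. The rho of 0.0737 between neighbouring spots of different clones on array 2 needs no row length and is also above that SD. That rho argues against a shift by an odd number of positions too, since such a shift would place duplicates there. A shift by an even number keeps duplicates together. Smooth variation over slide 1 as the whole source is argued against by 278 genes with 2 clones printed apart. These clones agreed weakly on array 1 (rho 0.164, Pearson r 0.29, permutation p = 0.0064, two-sided), well below the rho of 0.60 between duplicate spots. On array 2 they gave a rho of 0.036 (permutation p = 0.55). Spot noise was larger on array 2, with a median difference between duplicate spots of 0.316 against 0.161 on array 1, and how much a smaller difference between its RNA samples added stays open, as untested.

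The widest ratios of array 1 lay close together. Beside means adjacent in print order or about 1 row away, with the row length of 24 positions read from the values themselves. The random placements below used the same distances but do not allow for that choice. Of 46 clones with a spot over 3 in size on array 1, 73.9% lay beside another such clone, against at most 17.4% in 1000 random placements, which is consistent with local patches on the slide. Among the 20 genes of largest size on array 1, 10 held such a spot. Of the 12 named clones with such a spot, 8 lay beside another, among them CG5509 at -4.33 and Tengl4 at -4.26 on array 1, and 4 did not, among them CG10211 at 3.53. No clone was over 3 in size on both arrays, and no biological explanation was tested.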
